A study of Rattus norvegicus with 6 samples.

How the data were processed

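Messenger RNA was sequenced from the supraspinatus, a shoulder muscle of the rotator cuff, of rats with a rotator cuff injury. Per the labels, 3 samples came from rats treated with ultrasound and 3 from untreated control rats, all at 6 weeks. The ultrasound was given by a flexible patch in sessions of 10 min, 3 times per week, per the series description. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was enriched with oligo(dT) beads, and paired-end libraries were read on an Illumina NovaSeq instrument. The labels name no batch, date or cage. They do not say that the 3 samples of a group came from separate animals, so the p-values measure the spread between these samples.

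The authors deposited 1 table of FPKM (fragments scaled by gene length and by the mapped fragments of the library), with 32623 rat Ensembl gene identifiers in rows and 1 column per sample. The genome build was mRatBN7.2, per the submitters' processing notes. The aligner, the counting tool, the annotation release and any filter are not given in the sources used here. Columns were matched to samples by the library name in each sample's description, and 0 columns were left unmatched. FPKM are not counts, so no count model was fitted. FPKM of a gene depends on all the other genes of that library, because the fragments of each library are divided by their total.

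The table gives no gene symbols, and the annotation table used here held Ensembl identifiers in 0 of its rows, so 0 identifiers could be paired with a symbol. For that reason 39 lists of marker and pathway genes, which had been fixed before the data were examined for a camera gene set test, were not tested, and the genes fixed in advance by symbol are not reported. Genes are named here by identifier only.

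Values were transformed to log2(FPKM + 1), with a pseudocount of 1 FPKM. Genes with a mean of at least 1 FPKM over the 6 samples were tested, which left 11767 genes. Ultrasound was compared with control in limma 3.58.1 (R 4.3.3) with an intensity trend and no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The naming rule fixed in advance took genes past the threshold whose groups did not overlap and whose higher group mean was at least 2 FPKM, by size of change, and left out genes with no symbol. Since no gene had one, that clause was dropped after the values were seen. Its other conditions were met by 11 genes that fell and 2 that rose. The rule allowed a longer list in each direction, but only the first 2 genes in each direction are named. Group differences of single measures per sample were tested by two-sided exact permutation of the 6 samples, for which 3 against 3 samples allow no p below 0.1.

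The depth of each library is not stated. Where 2 samples hold a few fragments of a low gene, the ratio of their FPKM takes the same value in many genes, and this value gives the ratio of their depths. It was read from genes above 0 and under 0.1 FPKM in both samples, relative to ultrasound 1. Between 45 and 87 genes lay within 0.015 on the log2 scale of the ratio taken for a sample, against 4 to 9.5 in windows of the same width beside it. Absolute depth stayed unknown, so no counting intervals are given.

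The limma step was tested on simulated data for this comparison, with the real means and within-group spread of the 11767 genes and 200 genes changed. At a log2 change of 1, 57% of the changed genes were recovered, at 2, 85.5%, and at 3, 96.5%. Between 3 and 6 unchanged genes were called. The simulation drew genes independently and did not include differences shared by many genes within a library. It also gave both groups the same spread in each gene. In the real samples the median standard deviation of a gene was 0.21 among controls and 0.14 among ultrasound samples. Of 1346 real genes lower by at least 1, 11 were called, so the recovered shares do not carry over to these samples.

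Alternatives covered the pseudocount, the filter, the scaling between samples, the variance model, sample weights, a block on the replicate number, the threshold, and leaving out each sample in turn. Same-numbered samples of the 2 groups were checked for shared deviations, and the values did not settle whether the numbers pair them.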

Results

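Expression was measured in 6 supraspinatus muscle samples from rats with rotator cuff injury, 3 treated with ultrasound and 3 untreated, 6 weeks on. The comparison asks which transcripts differed with ultrasound treatment of the injured muscle. Of 32623 genes in the table, 20371 were above 0 in at least 1 sample and 12252 were at 0 in every sample. Depths relative to ultrasound 1 were 1.04 for ultrasound 2, 0.971 for ultrasound 3, 0.916 for control 1, 1.14 for control 2 and 0.941 for control 3. The mean relative depth was 1.00 ± 0.0345 (SD, n = 3) with ultrasound and 0.998 ± 0.121 (SD, n = 3) without it (exact permutation p = 1, two-sided).

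In the FPKM as deposited, transcripts that differed between the groups were mostly lower in ultrasound-treated muscle. Past the adjusted threshold, 11 of the 11767 tested genes fell and 2 rose (limma, Benjamini-Hochberg adjusted p under 0.05). The 11 genes that fell had log2 fold changes from -3.67 to -1.03, and in all 13 genes the 3 ultrasound values lay on one side of the 3 control values. At an unadjusted p under 0.05 there were 4107 genes lower and 301 higher with ultrasound. These counts moved with each sample left out. They were 6165 lower and 737 higher without control 1, 2259 and 132 without control 2, and 2256 and 169 without control 3. Without ultrasound 1, 2 or 3 they were 2308 and 200, 2448 and 228, and 3515 and 170. With all 6 samples, a limma adjusted p under 0.10 gave 2957 genes lower and 180 higher, so the count also depended on the threshold. At the threshold of 0.05, the number of calls rested on control 1. Without that sample, limma called 5569 genes lower and 544 higher, and the 13 genes were among them. Without ultrasound 1, ultrasound 2, ultrasound 3 or control 3 in turn, 1, 0, 0 and 5 genes were called, and without control 2 there were 22. The split by direction moved with the scaling between samples. Median-of-ratios scaling and quantile normalization level a shift shared by most genes by design. A more even split under them was therefore built in and cannot show whether the general fall was real. With median-of-ratios scaling, 16 genes were called lower and 7 higher, and 2142 genes were lower and 2272 higher at an unadjusted p under 0.05. With quantile normalization the direction turned at that p, with 1679 genes lower and 2637 higher, while 12 genes were called lower and 5 higher. Without control 1, 2815 genes were called lower and 3266 higher with median-of-ratios scaling, and 2348 lower and 4016 higher with quantile normalization.

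Among the 11 called genes that fell, ENSRNOG00000051024 fell the most. This gene had 0.159 ± 0.130 FPKM (SD, n = 3) in ultrasound muscle and 13.9 ± 2.70 FPKM (SD, n = 3) in control muscle. Its log2 fold change was -3.67 with a standard error of 0.18 (limma adjusted p = 0.00284). The gene ENSRNOG00000001414 had 2.44 ± 0.502 FPKM with ultrasound and 19.2 ± 5.06 FPKM without it, a log2 fold change of -2.53 with a standard error of 0.21 (limma adjusted p = 0.0212). Of the 2 genes that rose, ENSRNOG00000051179 had 7.08 ± 0.859 FPKM with ultrasound against 1.55 ± 0.323 FPKM in controls. This was a log2 fold change of 1.67 with a standard error of 0.15 (limma adjusted p = 0.0252). The other, ENSRNOG00000001827, had 34.6 ± 1.47 FPKM with ultrasound against 14.3 ± 1.92 FPKM in controls, and its log2 fold change was 1.23 with a standard error of 0.12 (limma adjusted p = 0.0256). The call of ENSRNOG00000001827 was lost with quantile normalization (limma adjusted p = 0.0546), without the variance trend (0.0521) and with no filter on low values (0.0553). It was also lost with any sample but control 1 left out, at adjusted p from 0.0738 to 0.203. The calls of ENSRNOG00000051179 and ENSRNOG00000001414 were lost with no filter (0.0662 and 0.0553) and with any 1 ultrasound sample left out (0.120 to 0.181 and 0.111 to 0.181), and that of ENSRNOG00000051179 without control 3 (0.0878). The call of ENSRNOG00000051024 was lost without ultrasound 2 (0.0641) or ultrasound 3 (0.0512). All 4 genes were chosen for groups that do not overlap, so control 1 lay with the other controls in them, at 10.9 FPKM in ENSRNOG00000051024, where controls 2 and 3 had 14.5 and 16.2 FPKM.

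**Figure D1:**
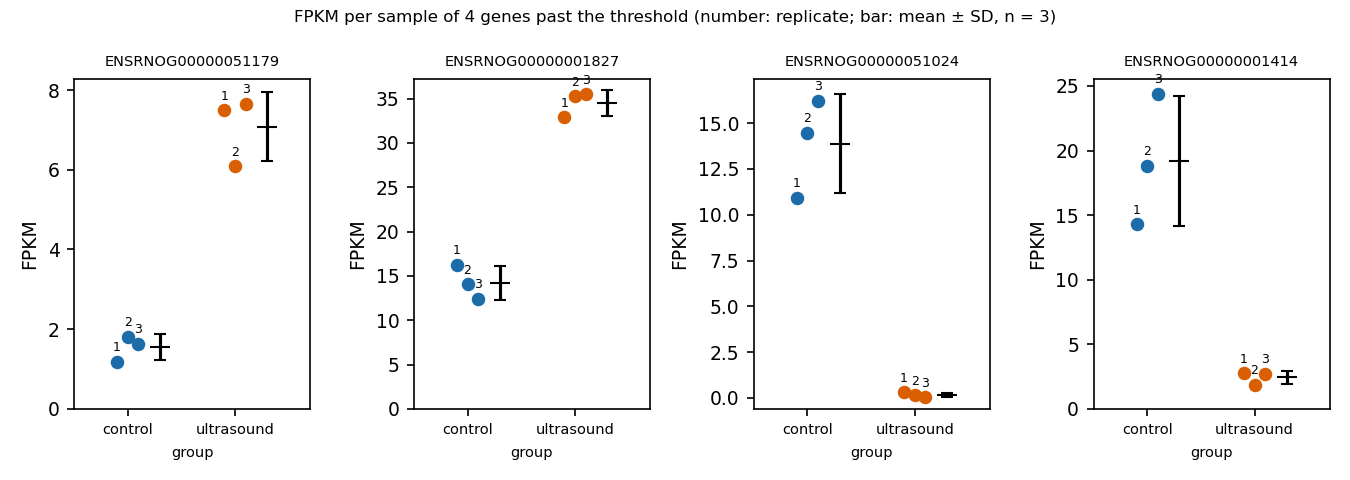
FPKM (linear axis) of ENSRNOG00000051179, ENSRNOG00000001827, ENSRNOG00000051024 and ENSRNOG00000001414 in each control and ultrasound sample, with the replicate number above each point and the mean ± SD (n = 3) beside each group. The first 2 genes are higher and the last 2 lower in all 3 ultrasound samples.

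Changes of a log2 unit or more were almost all decreases. There were 1346 genes lower by at least 1 on the log2 scale with ultrasound and 15 genes higher by at least 1. The decreases numbered 2041 without control 1, 985 without control 2 and 931 without control 3, and from 1264 to 1521 with an ultrasound sample left out. Of the 1346 genes, 1102 (81.9%) had all 3 ultrasound values below all 3 control values. Over all 1346 genes the median log2 difference from the ultrasound mean was 0.51 in control 1, 1.84 in control 2 and 1.83 in control 3. Over all tested genes, the groups did not overlap in 4295 genes lower and 487 higher with ultrasound, together 40.6% of genes. The average over all splits of the samples into 3 and 3 is 10%. Genes vary together, so a single split can lie far above that average without an effect of treatment. The shares of the other splits were not computed.

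In the FPKM as deposited, low and moderate transcripts were shifted down with ultrasound and the most abundant transcripts up. Among 7257 genes with a mean of 1 to 10 FPKM the median log2 fold change was -0.34, and 86.8% of them were below 0. That share was 55.1% with median-of-ratios scaling and 39.1% with quantile normalization. The medians were -0.16 in 3983 genes of 10 to 100 FPKM, 0.06 in 480 genes of 100 to 1000 FPKM and 0.27 in 47 genes of at least 1000 FPKM. The median of all genes was -0.26. The class of 100 to 1000 FPKM had no stable direction, with a median of 0.13 without control 1, -0.0071 without control 3 and -0.019 with each sample rescaled to a common sum. These directions depended on the scaling between samples. With median-of-ratios scaling the median of all genes moved by 0.32 to 0.05, and the class medians were -0.05, 0.20, 0.45 and 0.65 in order of abundance. With quantile normalization the median moved by 0.39 to 0.12, and the class medians were 0.11, 0.13, 0.18 and 0.07. The excess of large decreases was present under both, with 811 genes lower and 44 higher by at least 1 under the first and 648 lower and 64 higher under the second.

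**Figure D2:**
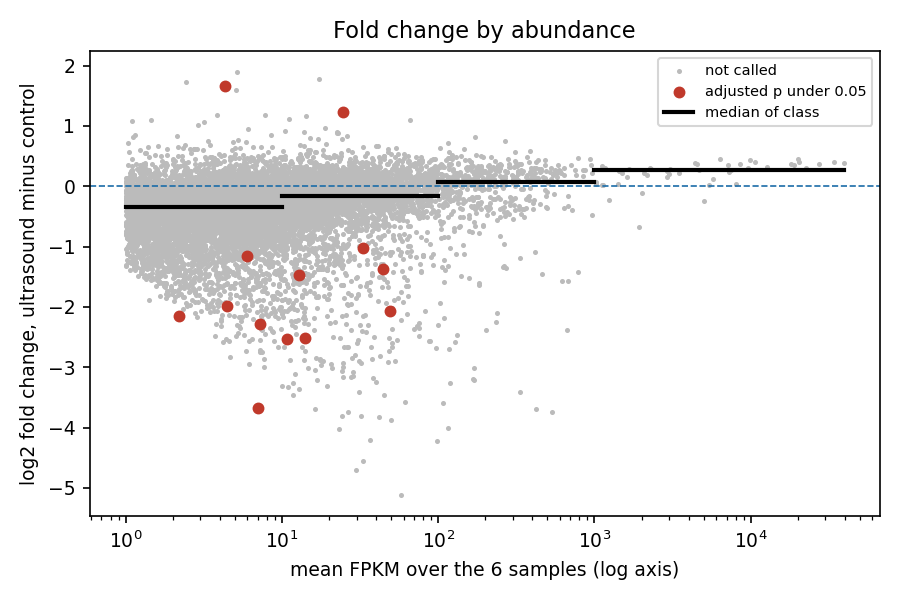
Log2 fold change (ultrasound minus control, on the log2(FPKM + 1) scale) of each of the 11767 tested genes against its mean FPKM over the 6 samples (log axis). Red points are the 13 genes past the adjusted threshold, and black lines are the medians of the 4 abundance classes, from -0.34 in the lowest to 0.27 in the highest in the FPKM as deposited; the class of 100 to 1000 FPKM turns to -0.0071 without control 3 and -0.019 with a common sum per sample, and under median-of-ratios scaling the lowest and highest classes were at -0.05 and 0.65, and under quantile normalization 0.11 and 0.07.

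Fewer genes reached 1 FPKM in ultrasound-treated muscle, and a few genes made up more of the signal. These are not separate results, since a larger share of the most abundant genes lowers the FPKM of the others. Genes at 1 FPKM or more numbered 10787 ± 235 (SD, n = 3) with ultrasound and 12125 ± 757 (SD, n = 3) without, with no overlap between the groups (two-sided exact permutation p = 0.1, the smallest that 3 against 3 samples allow). The control samples had 11252, 12541 and 12583 such genes for control 1, 2 and 3. The 10 most abundant genes held 39.4 ± 2.21% of all FPKM with ultrasound and 32.2 ± 3.62% without, again with no overlap (n = 3 per group, exact permutation p = 0.1). Genes above 0, a count that scaling does not change, numbered 16825 ± 103 (SD, n = 3) with ultrasound and 17943 ± 637 (SD, n = 3) without (exact permutation p = 0.1). This count is not a separate result either. A larger share of the most abundant genes leaves fewer fragments to detect the others. The counts and the share above were among 10 measures per sample compared this way, and the adjusted value of each was 0.125. The counts at 1 FPKM were not repeated under other scalings. There were 292 genes under 1 FPKM in every ultrasound sample and at 1 FPKM or more in every control. The opposite held for 4 genes. In the 9 other splits of the samples into 3 and 3, the highest such count in one direction was 108.

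**Figure D3:**
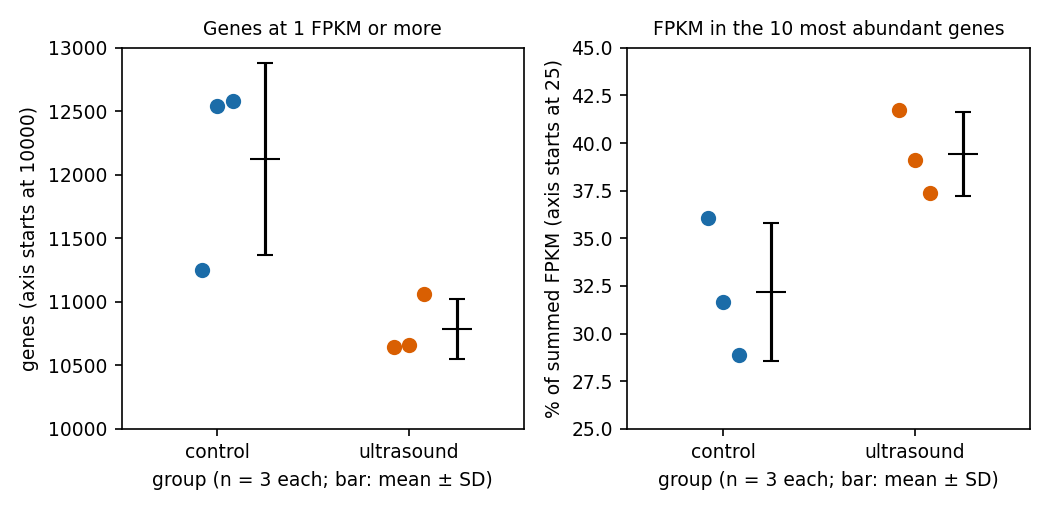
Genes at 1 FPKM or more (left; the axis does not start at 0) and percent of summed FPKM in the 10 most abundant genes (right; the axis does not start at 0) for each of the 3 control and 3 ultrasound samples, with mean ± SD. The ultrasound samples lie below every control on the left and above every control on the right, and control 1 is the control nearest to them in both.

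The control samples spread more widely than the ultrasound samples, with control 1 apart from controls 2 and 3. The median absolute log2 difference of a gene was 0.30 between controls 1 and 2, 0.35 between controls 1 and 3 and 0.12 between controls 2 and 3. Between pairs of ultrasound samples it was 0.13 to 0.18. The median standard deviation of a gene on the log2 scale was 0.21 among the controls and 0.14 among the ultrasound samples, and it was larger among the controls in 8138 genes (69.2%). Across genes, the ultrasound samples correlated with each other at Pearson's r from 0.987 to 0.989. Control 1 correlated with them at 0.978 to 0.979, and with controls 2 and 3 at 0.937 and 0.939. Controls 2 and 3 correlated with each other at 0.985 and with the ultrasound samples at 0.901 to 0.915. Genes are not independent replicates, so no p-value is attached. Control 1 was the control closest to the ultrasound mean in 72.4% of genes, where 33.3% would be even.

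**Figure D4:**
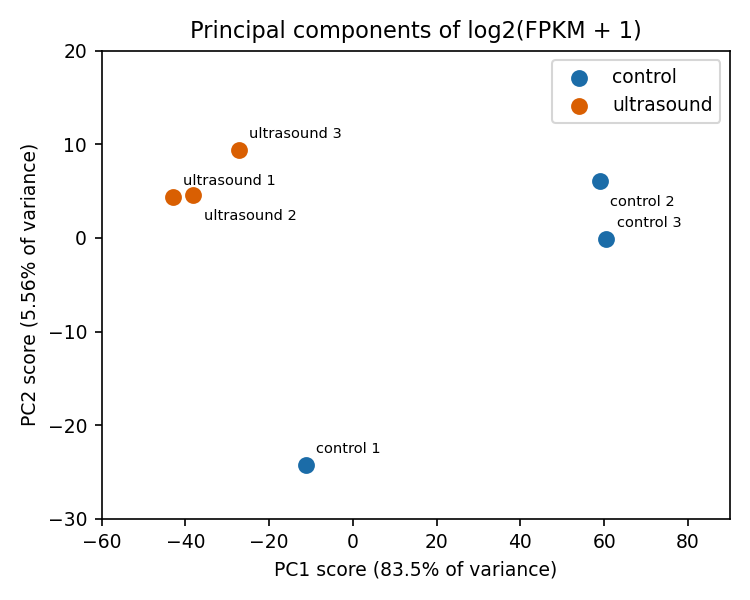
Scores of the 6 samples on the first 2 principal components of log2(FPKM + 1) over the 11767 tested genes, with 83.5% and 5.56% of the variance. On the first component the ultrasound samples lie from -43.0 to -27.2, control 1 at -11.2, and controls 2 and 3 at 59.0 and 60.5.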

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

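The number of called genes, 13 (11 of them lower), depended strongly on the samples, and less on most other choices. Leaving out 1 sample gave from 0 to 6113 genes, the highest without control 1. The count was 23 with a pseudocount of 0.1, 4 with no filter on low values, and 23 with median-of-ratios scaling. It stayed within 1.5 times of 13 under the other planned pseudocount, filter, scaling and variance settings. The genes called changed as well. Of the 13, 8 were called with median-of-ratios scaling, 8 with quantile normalization and 3 with no filter. Under the remaining settings of these kinds, from 9 to all 13 were called. A threshold of 0.10 gave 3137 genes (2957 lower). Sample weights gave 8313 genes, but the weights did not reach their convergence tolerance and set control 2 at 14.5 and control 1 at 0.112. The replicate block gave 933 genes (915 lower). Same-numbered samples correlated in their deviations from the group means at 0.23, -0.01 and 0.18. Ultrasound 1 and ultrasound 3 correlated best with the control of the same number, and ultrasound 2 with control 3, at 0.02. These few values do not settle whether the numbers mark pairs, and the numbers were not taken as pairs. Scaling moved the split of the calls between higher and lower: 69.6% of the calls were lower with median-of-ratios scaling and 70.6% with quantile normalization, against 84.6%. Added after seeing the data, removing the 100 most abundant genes and rescaling gave 21 genes. Also added then, leaving out control 1 gave 6081 genes (3266 higher) with median-of-ratios scaling and 6364 (4016 higher) with quantile normalization. The median log2 fold change turned from -0.26 to 0.052 with median-of-ratios scaling and 0.12 with quantile normalization, and without control 1 to 0.063 and 0.17. Both methods level a shift shared by most genes by design, so this turn cannot tell whether the fall was real. The 4 named genes kept their direction in every alternative run, and lost their call in 19 of 79 alternative fits, 14 of them with a sample left out. They were chosen as large changes without overlap of the groups, so most alternatives could not have turned their direction. The cause of the other moves was not tested. The set tests of the 39 gene lists, with their alternatives, were not run, since no identifier could be paired with a symbol. Absolute depth is unknown, so counting error could not be separated from the spread between samples.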

Other observations

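Of the tests below, those on removing the 100 most abundant genes were written down before their result was seen, and those on depth, on labels and on other splits were chosen after.

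Control 1 resembled the ultrasound samples more than controls 2 and 3, and the number of calls rests on it, with 13 genes with it and 6113 without it. Relative depth argues against depth as the cause through control 3: control 1 lay 0.0258 from control 3 and 0.0879 from the ultrasound mean, a difference of 0.0621, yet control 3 stood apart in expression, while control 2, the deepest library, lay 0.221 from control 1. The distance of control 1 to the ultrasound mean was 0.519 of that to the mean of controls 2 and 3. It was 0.543 with the 100 most abundant genes removed and the rest rescaled. A shift of all other genes through the share of those 100 therefore does not account for the pattern alone. Their share still went with it, at 64.4% in control 1, 65.4% to 69.2% with ultrasound, and 57.6% and 55.6% in controls 2 and 3. If controls 2 and 3 show untreated muscle, a swap of labels between the groups would place a sample like them among the ultrasound samples. The lowest correlation within ultrasound exceeded the highest of ultrasound with those controls by 0.0724, which argues against a swap on that condition alone. If untreated muscle resembled control 1 instead, this test could not detect a swap. One wrong label or an outside sample cannot be told apart from an animal that took another course. The best correlation of control 1 with an ultrasound sample differed by -0.00804 from the lowest within ultrasound, and 1 library decides it. Nor do the values show whether control 1 or controls 2 and 3 were the unusual controls. In the 1346 genes lower by at least 1, the median difference from the ultrasound mean was 1.84 and 1.83 in controls 2 and 3, against 0.51 in control 1.

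In the FPKM as deposited, most genes were lower with ultrasound, with a median log2 fold change of -0.26. That median was 0.052 with median-of-ratios scaling and 0.12 with quantile normalization, which level such a shift by design. The groups' ranges of relative depth overlapped by 0.0687, which argues against total depth as the cause of the fall. FPKM are already divided by the fragments of each library, so this test is a weak one. Depth outside the most abundant genes was not examined. After the 100 most abundant genes were removed and the rest rescaled to a common sum, the median was -0.0586 and 56.8% of genes were below 0, against 79.1% before. The 100 most abundant genes held 67.7% of FPKM with ultrasound against 59.2% without. Rescaling lifts the other genes of the ultrasound samples whatever the source, so a rise of a few abundant genes and a general fall of the others cannot be told apart in values that are relative within each library. Whether the difference in shares reflects treatment, the piece of muscle sampled or its cell content was not tested, because no marker gene could be named.

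Of the 10 splits of the 6 samples into 3 and 3, only 1, the real one, gave 13 genes, and the highest of the others gave 1. With 10 splits the share cannot fall under 0.05.

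The table holds 197 genes above 0 whose values equal those of another gene in all 6 samples, 121 of them above 0 in 1 sample alone. Of these, 12 were tested and 0 were called.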
